A study of Pimephales promelas with 23 samples.

How the data were processed

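Gene expression was measured in ovaries of female fathead minnows (Pimephales promelas), a small fish widely used in toxicity tests. Fish had been exposed to prochloraz, an imidazole fungicide known to inhibit cytochrome P450 enzymes including aromatase, or kept as controls, and were sampled at 6, 12 or 24 h. The labels used here do not give the concentration of prochloraz. There were 23 arrays: 4 controls at each time, 4 prochloraz samples at 6 h and at 12 h, and 3 at 24 h. Groups, times and replicate numbers were taken from the labels. For prochloraz 6 h replicate 1 the treatment protocol text names the control, whereas its title, source name and characteristics name prochloraz; it was kept as prochloraz. The labels do not state that each replicate came from a different fish, so p-values measure the spread between these samples only.

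Per the labels' protocols and the series design text, total RNA was labelled with Cy3 by the Quick Amp kit and hybridised to a single-colour Agilent array. Signals were extracted with Agilent Feature Extraction 9.5, per the submitters' processing notes, and with version 9.5.3.1 per the file headers. The values used were the processed signal of each spot, a linear intensity from which the background had been subtracted, per the file headers. The mean and background median signals of the same spots, also linear intensity values in the deposited scanner files, were used for an alternative background correction. The deposited value table of the series also held linear intensity values. Its columns had medians of 10.7 to 143.5 and differed from the processed signal by at most 0.0072 on the log2 scale over all arrays, so it was uncentred processed signal, with no trace of a normalization between arrays. Rows of that table were matched to probes by the feature number, and every column of per-sample values was used. According to the series design text, the authors normalized the arrays in Rosetta Resolver with its default settings and called genes by an analysis of variance at an unadjusted p under 0.01; that normalization could not be rerun here.

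Each array held 15744 features, of which 536 were control spots and 15208 were probes of 60 bases. Control spots were left out. The processed signal was converted to log2 and the 75th percentile of each array's probes was subtracted, so a value of 0 lies at that percentile. Spots marked as non-uniform and not saturated were left out; there were 63 to 991 per array. Probes well above background on at least 3 arrays were kept (12566), and those with at least 2 measured spots in every group were tested (12042). The rules on non-uniform spots and on measured spots were set after the files were seen; the first fits instead allowed at most 6 missing spots in all (11977 probes), and that rule is among the alternatives. The group means of all 23 arrays were fitted together with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 17 residual degrees of freedom). Prochloraz was compared with control at each time and as the average of the 3 differences. The difference of the effect between times and the change with time in controls were tested by a moderated F. P-values were adjusted by the Benjamini-Hochberg method over the probes tested, with a threshold of 0.05. All p-values of single probes below are from limma. Intervals are 95% confidence intervals from that fit.

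The files pair no probe with a gene name: the description of all 15208 probes is "Unknown", and their other identifiers name sequences (contigs, database entries or clone reads). Of these identifiers, 0 were found in the RefSeq gene table. The 24 gene lists fixed before the data were examined (steroid synthesis, oocyte and follicle genes, stress, other cell types and others) could therefore not be applied, and 0 were tested. The rule for named genes was to name those past the threshold with the largest changes and otherwise those of lowest p. Without gene names it was limited to probe identifiers: the 2 probes of lowest p in each direction per treatment comparison, and the 2 of lowest p for each F test. Since these probes were chosen on the same arrays, their intervals, signs within slides and lack of overlap describe them and are no further evidence. No genome positions are given in the files for these probes.

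The lowest signal well above background sets a floor on each array. Where a probe was not well above background on any array of a group, the difference is given as a bound: the brighter group's mean against the dimmer group's mean of, per array, the higher of that floor and the probe's own value. The arrays lay on 3 slides of up to 8 arrays. Each slide had been scanned once and extracted in 1 run, so slide, scan and extraction batch were the same division of the arrays. Slide was tested as a block and within slides. Each fit within 1 slide had 2 residual degrees of freedom and at most 2 arrays per group, so 0 calls there say little. The number of arrays limits the precision: the residual SD of log2 values had a median of 0.57 over probes, with quartiles of 0.36 and 0.97.

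The fit was tested on simulated values for all 12042 probes, drawn from normal distributions with the real residual SDs and 200 probes changed. For the 6 h comparison, 14 of 50 probes changed by 1 on the log2 scale were recovered, 28 of 50 changed by 2 and 46 of 50 changed by 4. For 12 h these numbers were 8, 25 and 40 of 50, and for 24 h they were 11, 24 and 42 of 50. For the average over times they were 31, 42 and 49 of 50. Between 1 and 14 unchanged probes were called per simulated comparison. The simulation gave all arrays independent noise of equal size for a probe, and the 200 changed probes eased the adjusted threshold. At an unadjusted p under 0.05 lay 4.56% of its unchanged probes at 6 h and 5.02% at 12 h. In the real fits it was 7.22% and 1.44% of all probes. The simulation thus differs from the real arrays, and the numbers recovered do not give the sensitivity there. The closed-form version of the fit used for splits of the arrays gave the same p-values as limma on the real data.

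Alternatives fixed before the data were examined were normexp background correction (offset 50), quantile normalization, median centring, the deposited value table, no filter on dim probes or a filter of 12 arrays, slide and replicate number as blocks, fits to the compared groups alone, array weights, a trended robust prior, the methods' analysis of variance, an adjusted p under 0.1 and leaving out each array. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.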

Results

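Ovary RNA of female fathead minnows was measured on 23 single-colour arrays, with 4 control samples at each of 6, 12 and 24 h and 4, 4 and 3 prochloraz samples at those times. Between 9293 and 11867 of the 15208 probes were well above background on 22 of the arrays. On the remaining array, control 6 h replicate 4, 5235 probes (34.4%) were well above background, and its 75th percentile of intensity was 62.9 against 734 to 1856 on the others. Its median correlation with the other arrays over probes was 0.843, against 0.946 to 0.956 for the rest. The median correlation across probes was 0.951 over 33 pairs of arrays of the same group and 0.952 over 220 pairs of different groups. The probes carry identifiers of sequences (contigs, database entries or clone reads) and no gene names, so results are given by probe.

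**Figure D1:**
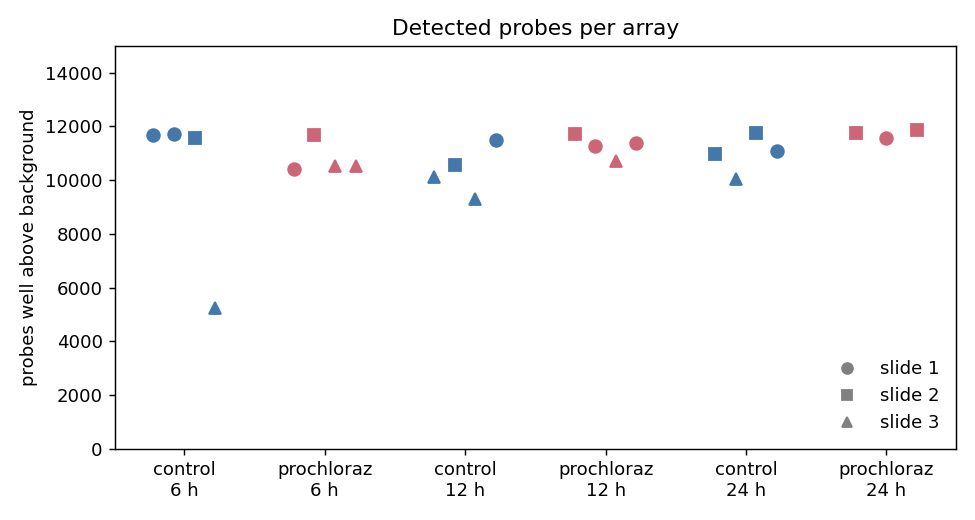
Number of probes well above background on each array (vertical axis, count), by group along the horizontal axis and by slide as the marker shape; each point is 1 array. All arrays lie between 9293 and 11867 except control 6 h replicate 4, at 5235.

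The first question was which ovarian transcripts differed after 6 h of exposure. The probe of lowest p, UF_Ppr_AF_109166 (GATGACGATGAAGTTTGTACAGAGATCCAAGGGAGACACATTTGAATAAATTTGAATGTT), had a mean log2 value of -5.91 ± 1.43 (SD, n = 4) in control and -8.69 ± 0.05 (SD, n = 4) in prochloraz ovaries (adjusted p = 0.658). It was well above background on 3 of 4 control arrays and on 0 of 4 prochloraz arrays. Control was at least 1.69-fold higher, or at least 1.06-fold without control 6 h replicate 4, whose spot was not well above background; leaving out control 6 h replicate 1 or prochloraz 6 h replicate 2 as well left no bound above 1. UF_Ppr_AF_103380 was well above background on the same numbers of arrays, with control at least 3.54-fold higher, or at least 2.68-fold without that array (adjusted p = 0.658). This rested mostly on control 6 h replicate 3, at -1.66 against -7.23 and -6.87 on replicates 1 and 2: without replicate 3 the bound was 1.69-fold, and without replicates 3 and 4 no bound above 1 was left. Higher values in prochloraz were measured for UF_Ppr_AF_116716, by 0.89 on the log2 scale (interval 0.41 to 1.38, adjusted p = 0.658). UF_Ppr_AF_112650 was higher by 1.11 (interval 0.50 to 1.71, adjusted p = 0.658). For each of these 4 probes the groups did not overlap array by array, and the sign was the same within all 3 slides. Both traits follow largely from choosing the probes by their p on these arrays. On slide 3 the only control was control 6 h replicate 4, whose spots for these 4 probes were not well above background. None passed the adjusted test. After normexp correction, which shrinks dim probes, the fitted differences of UF_Ppr_AF_109166, UF_Ppr_AF_103380, UF_Ppr_AF_116716 and UF_Ppr_AF_112650 were -1.22, -1.80, 0.29 and 0.03 with all arrays, and UF_Ppr_AF_112650 differed by 2.20 after quantile normalization.

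Across the 12042 probes tested at 6 h, limma called 0 at an adjusted p under 0.05, and 869 had an unadjusted p under 0.05, of which 737 were lower and 132 higher in prochloraz. An unadjusted p under 0.05 would be reached by 602 probes on average by chance alone if no probe differed. Probes that vary together widen the spread around that number. This balance depended on control 6 h replicate 4: without it 303 probes had an unadjusted p under 0.05, 184 lower and 119 higher, and 0 were called. Leaving out control 6 h replicate 1, 2 or 3 instead gave 1667, 1574 and 1346 probes. With all arrays the median fold change of all probes was -0.18 on the log2 scale. It was -0.59 after normexp correction, 0.08 after quantile normalization and 0.14 after median centring, where 450 probes were higher and 436 lower. After quantile normalization 451 were higher and 289 lower. Dim probes carried the shift: in the lowest of 4 equal bins of probes by mean signal the median was -0.96, and -0.16 without that array. The fit to the 6 h arrays alone gave 323 and array weights 369, with 0 called. With slide as a block 0 probes were called and 1538 had an unadjusted p under 0.05. Within slides 1 and 2, each also with 2 residual degrees of freedom, limma called 0 probes. Within slide 3, where control 6 h replicate 4 was the only control at this time, it called 2872, with 2 residual degrees of freedom and that array assumed to vary like the others.

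At 12 h the comparison again asked which transcripts differed between exposed and control fish. UF_Ppr_AF_117443 (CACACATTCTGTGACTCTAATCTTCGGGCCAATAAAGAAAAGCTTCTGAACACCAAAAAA) had the lowest p, with means of -2.54 ± 0.28 (SD, n = 4) in control and -4.29 ± 1.26 (SD, n = 4) in prochloraz, and the arrays of the groups overlapped (adjusted p = 0.9997). UF_Ppr_AF_109229 was lower in prochloraz, by -0.69 on the log2 scale (interval -1.07 to -0.32), with no overlap of arrays. Of the probes with higher values, UF_Ppr_AF_109846 differed by 0.98 (interval 0.44 to 1.52), with no overlap of arrays, and it was well above background on 2 of 4 control and 4 of 4 prochloraz arrays. UF_Ppr_AM_120594 differed by 1.12 (interval 0.41 to 1.82), with overlap of arrays. The sign was the same within all 3 slides for these 4 probes, and the adjusted p was 0.9997 for each. After normexp correction UF_Ppr_AF_109846 differed by 0.05.

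At 12 h limma called 0 probes, and 173 of 12042 (1.44%) had an unadjusted p under 0.05, with 119 higher and 54 lower. Without control 6 h replicate 4, which is not in this comparison but adds to the pooled spread, the number was 332, and without prochloraz 12 h replicate 3 it was 302; 0 were called in both. After median centring 88 probes were higher and 100 lower. The number was 36 after normexp correction, 337 in the fit to the 12 h arrays alone and 399 with array weights. With slide as a block 217 probes had an unadjusted p under 0.05, and 0 were called with that block or within any of the 3 slides. The interval of the fold change lay wholly within 1 on the log2 scale for 5402 probes (44.9%), and its median half-width was 0.84, so changes of more than 1 were not excluded for the remaining probes.

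At 24 h UF_Ppr_AF_111163 (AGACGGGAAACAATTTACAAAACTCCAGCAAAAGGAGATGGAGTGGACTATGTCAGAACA) had the lowest p, with -3.35 ± 0.32 (SD, n = 4) in control and -4.50 ± 0.55 (SD, n = 3) in prochloraz (adjusted p = 0.999). UF_Ppr_AF_110940 was lower by -1.37 on the log2 scale (interval -2.09 to -0.65), with 2 of the 3 prochloraz spots measured. UF_Ppr_AF_100202 had higher values in prochloraz, by 1.16 (interval 0.52 to 1.79). UF_Ppr_AF_117592 was well above background on 3 of 3 prochloraz arrays and 0 of 4 control arrays at 24 h, at least 1.53-fold higher. The adjusted p was 0.999 for each of these 4 probes. Their arrays did not overlap between the groups, and the sign was the same on both slides that held each group at this time. After normexp correction the fitted differences of UF_Ppr_AF_111163, UF_Ppr_AF_100202 and UF_Ppr_AF_117592 were -0.69, 0.73 and 0.12, and the last lies below the bound given.

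At 24 h limma called 0 probes, and 263 (2.18%) had an unadjusted p under 0.05, with 109 higher and 154 lower. Without control 6 h replicate 4 the number was 430, again with 0 called. The fit to the 24 h arrays alone called 1 probe, UF_Ppr_AF_108259 (adjusted p = 0.00805), and 237 probes were higher and 243 lower at an unadjusted p under 0.05. The number was 521 with array weights and 85 (31 higher, 54 lower) after normexp correction, with 0 called. With slide as a block it was 310, and 0 probes were called with that block or within slides 1 and 2; slide 3 held no prochloraz sample of this time.

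Averaging the 3 differences asked whether any transcript differed in the mean over the times. UF_Ppr_AF_112989 (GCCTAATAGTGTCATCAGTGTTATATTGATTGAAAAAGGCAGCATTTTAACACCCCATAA) was the probe of lowest p. Its prochloraz means were -0.07 ± 0.15 (SD, n = 4), 0.02 ± 0.19 (SD, n = 4) and 0.01 ± 0.17 (SD, n = 3) at 6, 12 and 24 h, and its control means were -0.69 ± 0.42, -0.36 ± 0.06 and -0.68 ± 0.31 (SD, n = 4 each). The average difference was 0.56 on the log2 scale (interval 0.32 to 0.81) and the adjusted p was 0.980. It was positive in 8 of 8 differences within a slide and time. UF_Ppr_AF_111793 differed by 0.74 (interval 0.35 to 1.12) and was also positive in 8 of 8. UF_Ppr_AF_109672 and UF_Ppr_AF_107773 had lower values in prochloraz in 7 of 8 and 8 of 8 such differences. Both lay near background: UF_Ppr_AF_107773 was well above it on 1, 2 and 3 of 4 control arrays at 6, 12 and 24 h and on no prochloraz array, a difference of at least 1.04-fold. No bound above 1 was left without control 6 h replicate 4, nor on leaving out control 6 h replicate 1, prochloraz 6 h replicate 2, control 12 h replicate 1 or control 24 h replicate 1 or 4. The adjusted p was 0.980 for these probes too.

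For the average limma called 0 probes, and 418 (3.47%) had an unadjusted p under 0.05, 129 higher and 289 lower. Without control 6 h replicate 4 there were 261 higher and 248 lower, after quantile normalization 241 and 176, and after normexp correction 42 and 205. Leaving out control 6 h replicate 2 gave 735 at an unadjusted p under 0.05. With slide as a block there were 430, with 0 called, and 0 were called within slides 1 and 2. The interval lay within 1 on the log2 scale for 8526 probes (70.8%).

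**Figure D2:**
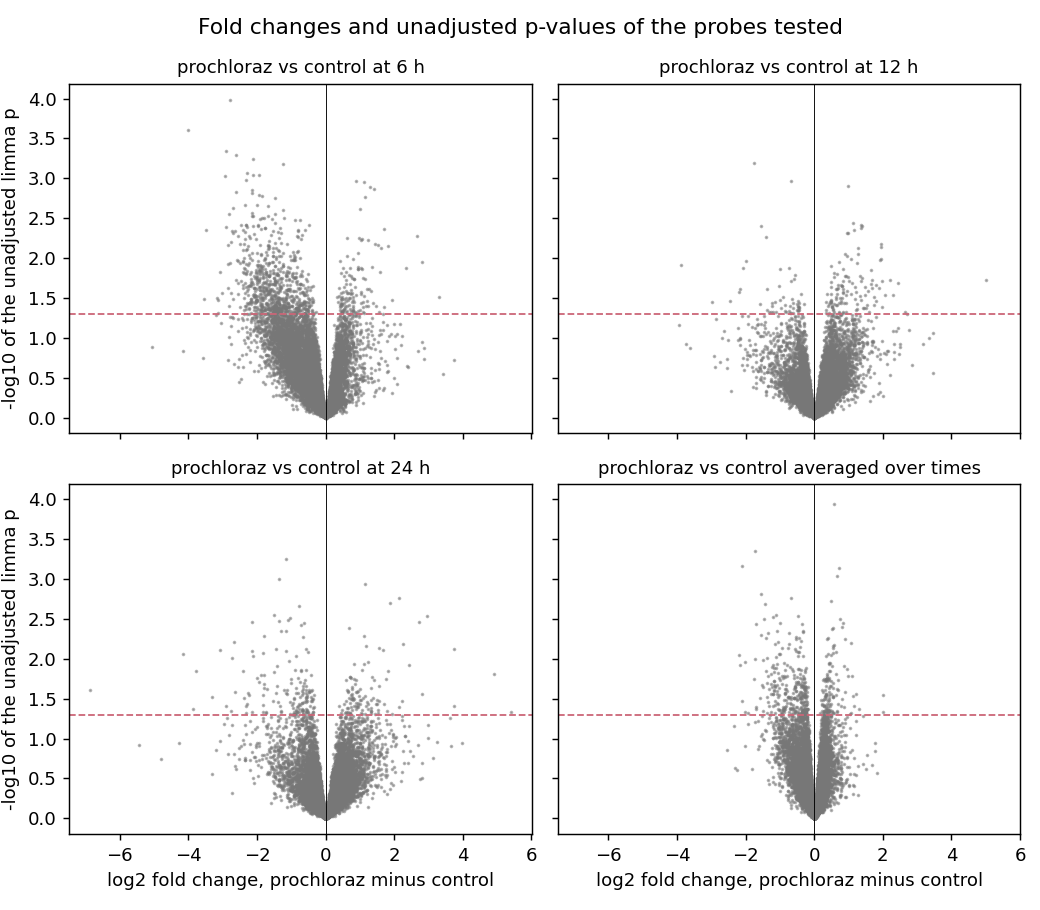
Log2 fold change of prochloraz over control (horizontal axis) against -log10 of the unadjusted limma p (vertical axis), 1 point per probe for 12042 probes, in 4 panels for 6, 12 and 24 h and their average; the dashed line marks an unadjusted p of 0.05. Points above the line number 869, 173, 263 and 418, and those at 6 h lean to lower values (737 against 132).

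**Figure D3:**
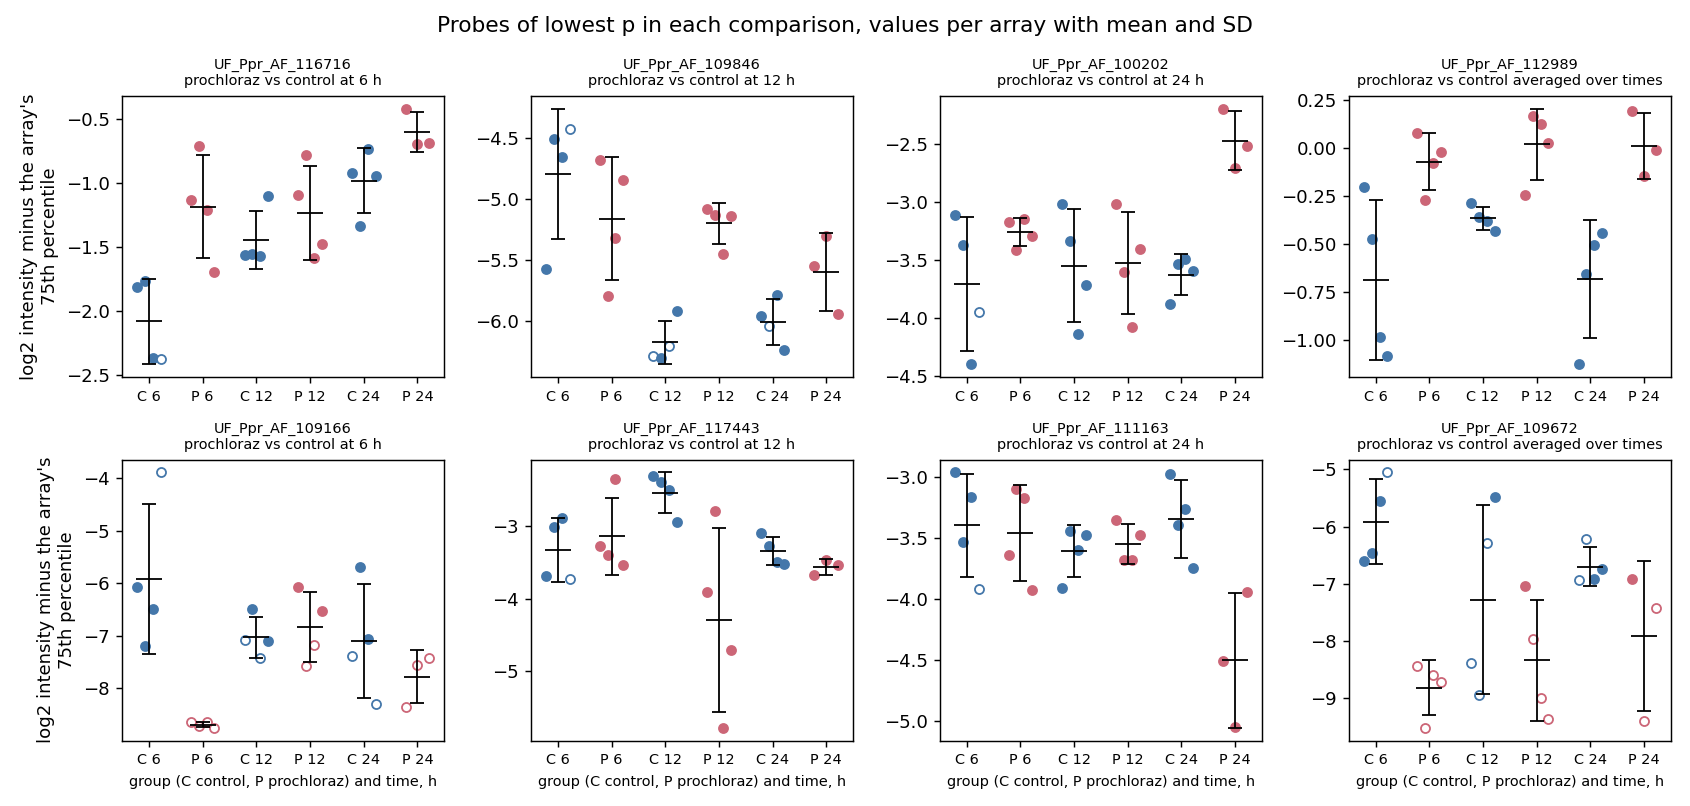
Log2 intensity minus the array's 75th percentile (vertical axis) of the probe of lowest p in each direction for each comparison, by group (C control, P prochloraz) and time in h; points are arrays, filled where well above background and open where not, and bars give the mean and SD. UF_Ppr_AF_112989 shows prochloraz means of -0.07, 0.02 and 0.01 above control means of -0.69, -0.36 and -0.68, while UF_Ppr_AF_109166 has 0 of 4 prochloraz arrays above background at 6 h.

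Whether the effect of prochloraz differed between times was tested directly. The lowest p belonged to UF_Ppr_AF_117592 (F = 15.4, adjusted p = 0.997), which was well above background on 3 of 4 control and 0 of 4 prochloraz arrays at 6 h and on 0 of 4 and 3 of 3 at 24 h. UF_Ppr_AF_117656 followed (F = 11.9, adjusted p = 0.997), with prochloraz means of -1.94 ± 0.45 (SD, n = 4) at 6 h and -3.54 ± 0.93 (SD, n = 3) at 24 h against control means of -3.64 ± 1.22 and -1.74 ± 0.87 (SD, n = 4 each). Limma called 0 probes, and 329 (2.73%) had an unadjusted p under 0.05, or 555 and 511 without control 6 h replicate 1 or 2 and 73 after normexp correction. With slide as a block there were 598, with 0 called, and 0 were called within slides 1 and 2. Each pair of times tested alone also gave 0. Across the 12042 probes, the fold changes at pairs of times correlated with r = -0.07 (6 and 12 h), 0.02 (6 and 24 h) and 0.07 (12 and 24 h). The pairs share no arrays, probes are not independent replicates, and leaving out arrays in turn gave standard errors of 0.11, 0.16 and 0.13 for these r.

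Control fish gave the background of change with time. UF_Ppr_AF_109846 had the lowest p (F = 17.1, adjusted p = 0.660), with control means of -4.79 ± 0.53 at 6 h, -6.18 ± 0.18 at 12 h and -6.01 ± 0.19 at 24 h (SD, n = 4 each). UF_Ppr_AF_117592 followed (F = 13.3, adjusted p = 0.729), with -5.60 ± 1.41, -7.68 ± 0.54 and -8.27 ± 0.68 (SD, n = 4 each), and was well above background in controls only at 6 h. Its 6 h mean was raised by control 6 h replicate 4, at -3.52 and not well above background, against -6.61 to -6.00 on the other 6 h controls. Limma called 0 probes, and 785 (6.52%) had an unadjusted p under 0.05. There were 300 after normexp correction, 339 in the fit to the control arrays alone and 462 with array weights, with 0 called. Without control 6 h replicate 4 there were 414, and without control 6 h replicate 1 or 2 there were 1343 and 1480; without replicate 1 limma called 1 probe, UF_Ppr_AF_109846 (adjusted p = 0.032, against 0.032 to 0.9998 over 29 alternatives). With slide as a block there were 1254, with 0 called. Within slides 1 and 2 limma called 0, and within slide 3, whose only 6 h control was replicate 4, it called 1866.

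Presence and absence of signal was also compared, without control 6 h replicate 4. At 6 h 63 probes were well above background on all 3 control arrays and none of the 4 prochloraz arrays, and 0 showed the opposite. At 12 h 10 probes were above background on all 4 prochloraz arrays alone, and at 24 h 35 on all 3 prochloraz arrays alone, with 0 in the opposite direction at both times. Other splits of the same arrays gave up to 261, 143 and 86 such probes, and 4, 10 and 7 of the 35 splits at each time, the real one included, gave at least as many. These splits ignored slide. Arrays of slide 3, control 6 h replicate 4 apart, had 9293 to 10726 probes well above background, against 10427 to 11867 on slides 1 and 2. At 6 h slide 3 held 2 prochloraz arrays and, of the controls, only replicate 4. It held 2 control and 1 prochloraz array at 12 h, and 1 and 0 at 24 h. The group with more slide 3 arrays lacked signal each time, so slide and treatment cannot be told apart in the direction of these counts. A slide difference alone would not give a counted probe, since slides 1 and 2 held both groups at each time. Other variation between arrays is needed too.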

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

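The tests of the dim array and of the lean at 6 h were chosen after those results were seen; the counts of splits were planned before. Of 102 groups of 4 arrays examined, 6 held a value standing apart, where chance gives about 5.1.

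Control 6 h replicate 4 stood apart from its group, with 5235 probes well above background against 11560 to 11724 on the other 3 arrays, and a median correlation with other arrays of 0.843 against 0.946 to 0.954. The other 3 control arrays at 6 h (11560 or more) lay above the lowest array of the other groups (9293), which argues against a state of control fish at that time. Too little sample RNA with otherwise normal labelling is argued against by the spike-in controls, whose median was 7.55 on the log2 scale against at least 10.4 on every other array. Relative to the median of the other arrays the sample signal fell by -4.55 on the log2 scale and the median of the spike-ins by -3.67. The spike-ins did not fall equally, and this median and the distance below combine unlike falls. E1A_r60_n9 was 10.1 and E1A_r60_n11 10.7 on this array. On control 6 h replicate 2, of lowest spike-in median among the others, they were 14.2 and 12.9. Beyond this array, E1A_r60_n9 lay below E1A_r60_n11 only on control 12 h replicate 2, where both were 16.0. Spike-ins minus the 75th percentile lay 0.94 above the median of that quantity over the other arrays, within 2 SD (1.85) over all 22 of them. That spread was carried by control 12 h replicate 2 and prochloraz 24 h replicate 1: without both, the distance was 0.957 and 2 SD was 0.899. A weakening equal for all spike-ins would keep E1A_r60_n9 above E1A_r60_n11, so their values argue against it. Weaker labelling, hybridisation or scanning of the array in a less even form stays open and was not decided by this test.

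Among probes with an unadjusted p under 0.05 at 6 h, 84.8% had lower values in prochloraz, and 60.7% without control 6 h replicate 4. The dim array is thus a candidate source of part of this lean. With all arrays the share also depended on scaling: it was 49.2% after median centring, 39.1% after quantile normalization and 83.7% after normexp correction. Without control 6 h replicate 4 the lean was a division of 303 probes, fewer than the 592 that chance alone would give. A response to prochloraz in the remaining part stays open and was not tested separately.

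Prochloraz 6 h replicate 2 had 11672 probes well above background, against 10427 to 10533 on the other 3 arrays of its group. UF_Ppr_AF_116716 was -1.10 on control 12 h replicate 4 against -1.57 to -1.55 on the other controls of that time. UF_Ppr_AF_109846 was -5.45 on prochloraz 12 h replicate 3 against -5.14 to -5.08. UF_Ppr_AF_109229 was -1.85 on control 12 h replicate 1 against -2.14 to -2.12.

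Chance could not be excluded for any of the counts at an unadjusted p under 0.05. At 6 h 22 of the 35 splits gave at least the real 869 probes, and the highest other split gave 2179. At 12 h it was 32 of 35 for 173 probes, with up to 731 in another split, and at 24 h 22 of 35 for 263, with up to 523. For the average it was 52 of 100 drawn splits for 418 probes (highest other 1878), for the difference between times 70 of 100 for 329 (highest other 1237), and for time in controls 44 of 100 for 785 (highest other 2040). Some other splits of the average called up to 82 probes after adjustment, where the real one called 0. All these splits kept control 6 h replicate 4 in the fit. At 6 h every split placed it in 1 of the groups, and the real count was 869 with it and 303 without. For 6 h, the average, the difference between times and time in controls, the splits could thus hardly single out the real grouping. They were not repeated without that array.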

How the results depend on the processing

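The correlations under alternatives, the fits without control 6 h replicate 4 at 12 and 24 h or with a slide block, the fit keeping non-uniform spots, the rule of at most 6 missing spots in all and the surrogate variables were chosen after seeing the data. The counts of called probes stayed at 0 under background correction, normalization, value table, filter, slide block, weights, prior, the looser threshold and non-uniform spots kept, each changed alone. The rule of at most 6 missing spots in all, used in the first fits, called 0 probes alone. Combined with normexp it called 1 probe at 6 h and 1 for time in controls, and with median centring 1 at 6 h, 1 for the difference between times and 1 for time in controls. All were UF_Ppr_AF_107979 (lowest adjusted p = 0.00628), whose only measured control spot at 6 h lay on the dim array, control 6 h replicate 4; the rule of 2 spots per group, set after these counts were seen, leaves the probe out. Surrogate variables (2, 4 or 6, without that array) called 0 probes at each time and 0, 2 and 8 for the average, where 10 of 50 permutations of the labels gave at least 2 and 10 of 50 at least 8. The fit to the 24 h arrays alone called 1 probe, UF_Ppr_AF_108259 (4.91 on the log2 scale, adjusted p = 0.00805, the lowest of 25 alternatives, against 0.999 in the fit to all arrays and up to 0.9999995). Its SDs were 0.50 and 0.05 at 24 h and 2.66 to 3.57 in the groups at 6 and 12 h, which the fit to all arrays pools. The methods' analysis of variance at an unadjusted p under 0.01 gave 37, 52 and 89 probes at 6, 12 and 24 h and 29 for time in controls. In place of the average it compared all prochloraz with all control arrays, ignoring time, and gave 61. Each count was below the share of 0.01 of the 12042 probes tested that chance alone would give. After adjustment each was 0. Leaving out arrays in turn gave 0 calls, except 0 to 1 for time in controls. The correlation of effects at 6 and 12 h became 0.31 with normexp, 0.080 with no filter and -0.22 with the slide block, and that at 12 and 24 h became 0.23 with no filter; the cause was not tested. All 421 values of the 16 named differences kept their sign, and none passed the threshold. Their choice by p on the same arrays makes an unchanged sign likely. Sizes varied more: UF_Ppr_AF_112650 at 6 h ranged from 0.03 to 2.20 and UF_Ppr_AF_109846 at 12 h from 0.05 to 1.06. With the replicate block the counts were 0 for every comparison. Whether the numbers pair the samples was not settled, and no test of it was run. Of 11 same-numbered pairs, 3 had deviations correlating above 0.1 (-0.19 to 0.23), and 5 of 11 correlated best with their own number. Scan batch equalled slide and was not run apart. Gene lists could not be run, nor the methods' test for the difference between times; for it and the average, the compared groups are all arrays. Signal over background limits dim probes on control 6 h replicate 4.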

Other observations

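All tests of on/off probes were chosen after the pattern was seen. Some probes took 1 of 2 well separated levels across arrays. Over the 22 arrays without control 6 h replicate 4, 61 of 10820 fully measured probes (0.564%) had a gap of at least 3 on the log2 scale with at least 3 arrays on each side and every array of the high side well above background; the median gap was 4.07. UF_Ppr_AF_108259, chosen after its values were seen, ranged from -4.94 to 0.16 in control and from -5.80 to 0.19 in prochloraz ovaries at 6 h. Of the 61 probes, 1 at 24 h and 0 at 6 and 12 h were high on all arrays of a treatment and low on all of the other.

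Pairs of arrays shared these states unequally. The percent of probes in the same state had an SD of 8.76 percentage points over 231 pairs, above the highest SD in 1000 shuffles of the states within probes (7.42), which argues against independent defects of single spots. The pair sharing most, control 12 h replicate 3 and prochloraz 24 h replicate 2, agreed for 88.5%, little above the highest pair in those shuffles (86.9%). The 61 probes formed 60 different patterns of arrays, and the commonest pattern held 2 probes. In 1000 shuffles within probes and slides, which keep any effect of a slide on a probe, the SD was at most 7.40, which argues against slide as the only source. In 1000 shuffles within probes and groups of treatment and time it was at most 7.54, which argues against prochloraz exposure as the only source. The shuffles within slides and groups replaced a test on pairs of different slides or treatment, which a slide effect could also raise, and were added after tests on mean differences, in which arrays of 1 slide shared 0.69 percentage points more than arrays of different slides (permutation p = 0.263) and arrays of the same treatment within a time -2.13 relative to different treatment (permutation p = 0.904). Sharing and closeness in detected probes had a Spearman rho of 0.061 over pairs (permutation p = 0.221), so brightness stays open, as do sequence variants under the probes or differences between fish such as relatedness, which could not be tested with these labels. The adjusted p over the 4 relations tested, time included, was 0.525 or more.

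For 709 of the source sequences the array held a probe with AF and one with AM in its identifier; the files do not say what these letters mean. In 10 pairs the 2 probes shared 12 bases on opposite strands, and in 0 pairs on the same strand. For pairs sharing no such stretch the probe sequences alone do not tell the strands. The AF probe was the brighter in 538 pairs (75.9%), and the median of AF minus AM was 3.43 on the log2 scale. In 283 pairs only the AF probe was kept by the filter on signal above background, in 74 only the AM probe, in 274 both and in 78 neither. Spike-in medians stood at 13.7 on control 12 h replicate 2 and 12.997 on prochloraz 24 h replicate 1, where the median over arrays was 11.2.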
